A study of Mus musculus with 62 samples.

How the data were processed

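The deposited values were gene counts in 1 matrix, with a column per library, for 62 RNA-seq libraries of CD11b+ cells from mouse brain, which the series title calls microglia. Per the labels, the authors purified RNA with a miRNA easy kit and made libraries from 10 ng RNA with SMART-Seq v4 in 2 batches and in pools of 7 to 8. The authors sequenced them on a HiSeq 2500 with paired reads of 125 bp. The authors named Trimmomatic, TopHat and HTSeq with the genome mm10 and gave no versions. No molecular identifiers were used, so PCR copies count as reads. All counts, floors and depths here cover counting error only.

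The labels gave genotype and age. WT is wild type, NLRP3 lacks Nlrp3, APPPS1 carries the transgenes of an Alzheimer's disease model, and APPPS1_NLRP3 combines both. Ages were 4, 6 and 12 months (4m, 6m, 12m). Further 12-month libraries carry the tag Mxo4 in their titles, which the sources used here do not spell out, and they were kept as separate groups. The 16 groups held 3 to 5 libraries each. The labels do not say whether libraries come from separate animals. Titles end in 3 numbers. The first takes 8 values, each in 7 to 8 libraries, the second takes 2 values, each in 31 libraries, and the third runs from 1 to 62 and is called the replicate number here. No paired analysis was possible because each replicate number occurs once.

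Total counts per library were 18392142 at the median and 27604393 at most. APPPS1_6m replicate 21 held 659 counts. It stayed in the fit and was left out of group means and of counts of libraries, as any library under 100000 counts. NLRP3_12m replicate 45 held 1394435 counts and APPPS1_12m replicate 41 held 6187249. The next lowest total was 11484943 counts. The files listed 53801 gene identifiers, of which 53620 had a symbol in GENCODE vM21 (GRCm38, equal to mm10). Positions are given in GRCm38, 1-based. Sex was not labelled and was read from Xist (at least 100 CPM, counts scaled to library size) and the sum of 4 Y-linked genes (at least 50 CPM).

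Choices of groups, comparisons, tests, gene lists, named genes and the first set of alternatives were made before the data were examined. The test was the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3. All 62 libraries were fitted at once with TMM size factors, a term per group and a term for the second title number. The filter filterByExpr (minimum count 10, minimum total 15) left 19865 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, two-sided. Effects are log2 differences with standard errors (log2 difference divided by the square root of F). Levels are mean CPM with SD between libraries. The p-values measure only the spread between these samples.

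The 30 comparisons were 24 between 2 groups and 6 between 4 groups. The first kind were APPPS1 minus WT, NLRP3 minus WT, APPPS1_NLRP3 minus APPPS1 and APPPS1_NLRP3 minus NLRP3 at each age and with the tag, 12m minus 4m per genotype, and Mxo4 minus untagged at 12m per genotype. The second kind were interactions: the transgene difference without Nlrp3 minus that with Nlrp3 at each age and with the tag, and APPPS1 minus WT of the age and tag differences.

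The 29 gene lists were 17 of biology and 12 of other cell types or handling. The biology lists were homeostatic microglia, disease-associated microglia, type I interferon response, MHC class I presentation, MHC class II presentation, inflammasome and IL-1 family, NF-kB cytokines and chemokines, phagocytic receptors, lysosome, complement, cholesterol synthesis, lipid transport and storage, glutamine and glutamate metabolism, glycolysis, oxidative phosphorylation, proliferation and ribosomal proteins. The other lists were immediate-early and dissociation response and markers of neurons, astrocytes, oligodendrocytes, endothelium, monocytes, border-associated macrophages, neutrophils, T and NK cells, B cells, erythroid cells, and choroid plexus and ependyma. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 29 lists of a comparison. An estimated correlation was the alternative, and its adjusted p is given beside the preset one. Counts adjusted over the list alone are given beside counts adjusted over all genes. The glutamine and glutamate list was chosen knowing of work on these mice and is not independent evidence.

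Named genes were a fixed set that included Nlrp3, App, Prnp and Thy1, then up to 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group, then the 4 genes with the smallest adjusted p of each list with called members. Where nothing was called, the 3 smallest p were taken. Predicted genes, RIKEN clones, pseudogenes and identifiers without a symbol were counted, not named. Genes whose call held in every leave-out were preferred from that set, and those chosen after the values were seen are said to be so. Where a group lay at the floor (3 counts or fewer over the group), no fitted fold is given, except where its sign turned under an alternative. Such a value depends on the prior count and is no bound.

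The alternatives set beforehand were RLE size factors, no low-count filter, DESeq2 1.42.0, no term for the second title number, the first title number as a further term, a sex term, an estimated correlation and leaving out each library in turn. Alternatives chosen after the data were seen were leaving out the 3 shallowest libraries, leaving out the library labelled APPPS1_12m_Mxo4 replicate 56 and the near-empty library, RLE and DESeq2 each without the near-empty library, and the sex term without that replicate 56. Each comparison was also computed within each value of the second title number. There WT_12m, NLRP3_12m_Mxo4 and APPPS1_6m (usable depth) held 1 library with number 1. APPPS1_4m, NLRP3_12m, WT_12m_Mxo4 and APPPS1_12m_Mxo4 held 1 with number 2. Each was assumed to vary like the others.

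The test was tried on simulated counts with known effects of log2 0.5, 1 and 2. In APPPS1 minus WT at 4m, 2 of 67, 37 of 67 and 55 of 66 changed genes were called. False calls were 5 among 19265 others. Simulated differences of log2 0.5 were mostly out of reach at these group sizes. Exon use, splicing and variant reads were not analysed here.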

Results

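The libraries were made from CD11b+ brain cells of WT, NLRP3, APPPS1 and APPPS1_NLRP3 mice at 4, 6 and 12 months, with a tagged set (Mxo4) at 12 months. Nlrp3, the sensor of the NLRP3 inflammasome (ENSMUSG00000032691, chr11 59541568 to 59566956, + strand, 3 transcripts), lay between 60.4 and 271 CPM in the 30 libraries of groups with intact Nlrp3. It lay between 0 and 2.27 CPM in the 31 libraries of groups without it. Read from Xist and Y-linked genes, 42 libraries were female, 19 were male and 1 could not be read. All 3 WT_12m and all 5 APPPS1_12m libraries were female, whereas all 4 NLRP3_12m and all 4 APPPS1_NLRP3_12m libraries were male. All libraries of the 4-month groups were female. Between replicate pairs of 1 group, 90 in all, the chi-square per degree of freedom of the counts was 25.2 at the median, far above counting error. Differences are log2 values ± standard error with adjusted p from edgeR, and levels are CPM ± SD. For gene lists, brackets give in order the count adjusted over the list alone, the median difference, and the adjusted p with the preset and with an estimated correlation, or the last of these alone. Replicate numbers are unique, so a number names a library. A named gene kept its call when any 1 library of its comparison was left out, unless a replicate is named beside it.

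At 4 months, few genes separated APPPS1 from WT, and all 5 called genes rose in APPPS1. Cst7, which encodes the protease inhibitor cystatin F and marks disease-associated microglia (chr2 150570415 to 150578944, + strand), rose from 6.93 ± 1.95 CPM (n = 4) to 119 ± 26.2 CPM (n = 3). Its difference was 4.13 ± 0.65 (adjusted p = 0.0019), and all 3 APPPS1 libraries lay above all 4 WT libraries. Lpl, the lipase that frees fatty acids from lipoproteins (chr8 68880491 to 68907448, + strand), rose by 2.31 ± 0.46 (adjusted p = 0.037). Bcl2a1d, an inhibitor of apoptosis, rose by 2.22 ± 0.41 (adjusted p = 0.025), and Prnp, the prion protein gene (chr2 131909928 to 131938429, + strand), by 1.24 ± 0.24 (adjusted p = 0.028). App at 0.13, Thy1 at 0.55 and Nlrp3 at 0.07 did not pass. Of 25 disease-associated microglia genes, 2 rose (7 over the list alone). Their median was 0.49 (adjusted p = 1.35e-22, and 0.132 with an estimated correlation). Proliferation genes had a median of 0.37 (1.19e-10 and 0.132), with 2 rising over the list alone. Immediate-early genes, which respond to cell handling, had a median of −0.48 (1.89e-14 and 0.153). Neuron markers moved with the transgenes at a median of 1.19 (6.53e-06 and 0.482). In either value of the second title number, 3 genes were called. Only 1 gene was called without replicate 1, 7, 5, 6 or 3, and 2 were called without replicate 4. Lpl lost its call without replicate 1 (0.258), 4 (0.282), 6 (0.514), 3 (0.197), 7 (0.12) or 5 (0.25). Bcl2a1d lost it without replicate 1 (0.258), 6 (0.138), 3 (0.152), 7 (0.12) or 5 (0.148), and Prnp without replicate 1 (0.258), 4 (0.0811), 6 (0.138), 3 (0.589), 7 (0.0702) or 5 (0.148).

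At 6 months 602 genes were called in APPPS1 minus WT (410 higher, 192 lower, 67 of them predicted), with disease-associated and lipid genes among the rises. Cst7 reached 660 CPM in the 3 APPPS1 libraries with usable depth against 7.69 ± 2.02 CPM in WT (n = 5), a difference of 6.37 ± 0.63 (adjusted p = 6.8e-09). Baiap2l2, which shapes membranes through actin, rose by 6.94 ± 0.79, the calcium-permeable channel gene Trpm1 by 6.55 ± 0.94, and Dcstamp, needed for cell fusion, by 4.58 ± 0.70. Lpl rose by 4.45 ± 0.45, the beta-glucan receptor Clec7a by 3.44 ± 0.43, the receptor kinase Axl (chr7 25757273 to 25788705, − strand) by 2.90 ± 0.39 and Ch25h, which makes 25-hydroxycholesterol, by 2.61 ± 0.47. Hif1a, the regulator of glycolysis under low oxygen (chr12 73901375 to 73947530, + strand), rose by 1.24 ± 0.21 from 207 ± 10.2 to 503 ± 85.6 CPM. Some glycolytic genes rose, with Pkm at 0.86 ± 0.17, Pgk1 at 0.87 ± 0.17 and the lactate exporter Slc16a3 at 1.07 ± 0.21. Among lysosomal enzymes, Gusb rose by 0.87 ± 0.15 and Hexa by 0.89 ± 0.17. Psat1, an enzyme of serine synthesis that uses glutamate, rose by 2.13 ± 0.30, and Prnp by 1.44 ± 0.22. The immediate-early gene Fosb fell (−1.37 ± 0.31, adjusted p = 0.0069), a call lost without replicate 23 (0.0748) or 22 (0.0582). Each of these rises held in 3 of 3 APPPS1 libraries, all above the WT range. Growth hormone (Gh) and prolactin (Prl) were called, but nearly all their reads came from replicate 23, at 153 and 88 CPM, against at most 0.0487 and 0.0352 CPM in the other APPPS1 libraries. Their adjusted p without it was 0.993 and 0.992, and neither passed without WT replicate 20, 19, 17 or 18, nor Prl without 16.

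Of 25 disease-associated genes, 21 rose at 6 months (25 adjusted over the list alone, adjusted p = 0.0284 with an estimated correlation). Lipid transport genes rose in 8 of 19 (8 over the list alone, 0.0338). Glycolysis genes rose in 9 of 23 (12 over the list alone, with 1 falling; median 0.54, 0.0565), cholesterol synthesis in 6 of 20 (11; 0.42, 0.0601), proliferation in 6 of 22 (14; 0.55, 0.0565), lysosome in 11 of 24 (16; 0.46, 0.273) and ribosomal proteins in 2 of 20 (15; 0.46, 0.273). The bracketed values are the median and the adjusted p with an estimated correlation, and with the preset correlation all of these had an adjusted p under 0.05. Immediate-early genes fell in 8 of 22 (17; −0.84, 0.0565). Interferon genes had 0 of 22 called, 6 rising over the list alone (0.38, 0.378). The inflammasome list (0 up, 2 down of 22) and the glutamine and glutamate list (2 up, 2 down of 23) did not pass, at adjusted p = 0.929 and 0.204. Oligodendrocyte markers had 1 up and 1 down of 11 (median 0.68; adjusted p = 0.0463, and 0.346 with an estimated correlation). Neuron markers, at a median of 1.90 (0.202), again lay on the side of the rises, and endothelial markers, at −1.11 (0.22), on the side of the falls. The count was 424 with second title number 2 (number 1 left 1 usable APPPS1 library). Without replicate 20, 17, 23, 24 or 22, it was 361, 373, 250, 239 or 314. With the first title number as a further term, it was 119.

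**Figure D1:**
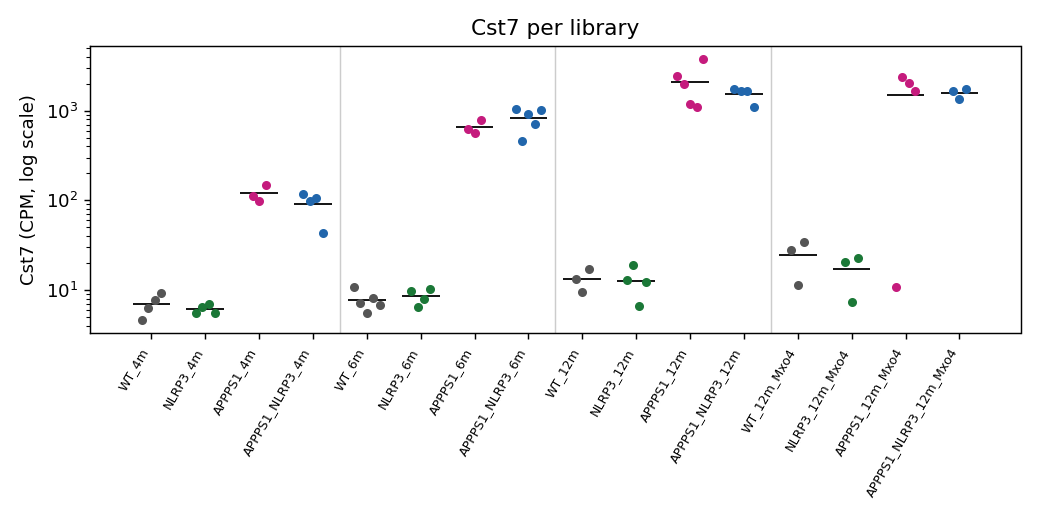
Cst7 level in CPM (log axis) for each library by genotype, age and tag, with points for libraries (the near-empty one left out) and lines for group means. WT means run from 6.93 to 24.4 CPM and APPPS1 means from 119 to 2106 CPM, and the library labelled APPPS1_12m_Mxo4 replicate 56 sits at 10.9 CPM.

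At 12 months 3590 genes were called in APPPS1 minus WT (2208 higher, 1382 lower, 493 of them predicted), with interferon, MHC class I and cytokine genes among the rises. Cst7 rose from 13.3 ± 3.87 CPM (n = 3) to 2106 ± 1101 CPM (n = 5), a difference of 7.29 ± 0.81 (adjusted p = 2.8e-08). Mamdc2, a matrix protein gene (chr19 23302609 to 23448442, − strand), rose by 7.40 ± 1.02, the lysosomal glycoprotein gene Gpnmb by 6.44 ± 1.14 and the Wnt antagonist Dkk2 by 6.33 ± 0.96. Apoe, the lipid carrier (chr7 19696109 to 19699188, − strand), rose from 1148 ± 259 to 10330 ± 3213 CPM, and Trem2, the lipid-sensing receptor, by 1.64 ± 0.23. Il1b, the inflammasome-processed cytokine (chr2 129364570 to 129371139, − strand), rose from 222 ± 70.8 to 1729 ± 464 CPM, a difference of 2.96 ± 0.38 (adjusted p = 1.9e-07). Its antagonist Il1rn rose by 2.44 ± 0.40, the chemokine Ccl3 by 1.67 ± 0.23, and the endotoxin co-receptor Cd14 by 1.49 ± 0.23. Interferon-induced Cxcl10 (chr5 92346638 to 92348889, − strand) rose by 1.68 ± 0.23, Ifitm3 by 2.23 ± 0.31 and Bst2 by 1.48 ± 0.20. The MHC class I genes B2m at 1.60 ± 0.23, H2-K1 at 1.34 ± 0.20 and H2-T23 at 1.13 ± 0.15 rose as well. Hif1a rose by 2.09 ± 0.23, lactate dehydrogenase Ldha by 1.33 ± 0.15, the fatty acid carrier Fabp5 by 4.27 ± 0.58, the lipid droplet gene Plin2 by 1.70 ± 0.23 and Psat1 by 2.93 ± 0.35. Lysosomal Cd68 and Gusb rose by 1.44 ± 0.20 and 1.21 ± 0.16, and the cell cycle kinase Cdk1 by 1.89 ± 0.28. Tmem119, a homeostatic marker (chr5 113793729 to 113800516, − strand), fell (−0.85 ± 0.17, adjusted p = 0.00013), from 2443 ± 414 to 1361 ± 194 CPM. Adgrg1 at −0.91 ± 0.17 and Crybb1 at −1.19 ± 0.24, both homeostatic, and the prostaglandin receptor Ptger3 at −2.53 ± 0.55 fell too. In each of these genes all 5 APPPS1 libraries lay beyond the range of the 3 WT libraries, except for Adgrg1, with 4 of 5.

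At 12 months all 25 disease-associated genes rose (median 2.82; adjusted p = 0.0121 with an estimated correlation), as did 20 of 22 interferon genes (22 over the list alone, 1.67, 0.0225) and all 20 ribosomal protein genes (1.37, 0.0225). MHC class I rose in 11 of 15 (14 over the list alone, 0.0225), NF-kB cytokines in 12 of 21 (15; 0.0236), inflammasome and IL-1 in 10 with 2 falling (11 and 3; 0.0225), and phagocytic receptors in 10 with 2 falling of 24 (13 and 4; 0.037). Lysosome genes rose in 17 (17; 0.0324), cholesterol synthesis in 12 with 1 falling (13 and 1; 0.0225), lipid transport in 10 (11; 0.0121), glycolysis in 13 with 2 falling (13 and 3; 0.0225) and proliferation in 14 (16; 0.0314). Oxidative phosphorylation rose in 16 of 23 (17; adjusted p = 7.64e-10, and 0.0675 with an estimated correlation), MHC class II in 6 of 10 (7; 0.000288 and 0.163), and complement in 4 of 16 (7; 0.00614 and 0.146). Homeostatic genes fell in 6 of 20 (7 fell and 1 rose over the list alone; median −0.29, 0.0129 and 0.511). Glutamine and glutamate genes split into 4 rises and 4 falls, with a median of −0.12, a mean of 0.01 and adjusted p = 0.857. Neuron markers lay lower, with 1 of 11 falling (median −1.83; 0.0135 and 0.511). Monocyte markers rose in 4 of 10 (5; 1.54, 0.0392 and 0.509), but their median was −0.209 without replicate 38, which carried the most neutrophil and monocyte reads of its group. B cell markers (1 up, 1 down of 5) did not pass at adjusted p = 0.661. The count was 606 with second title number 1 and 4841 with 2, and 2243 with the first title number as a further term.

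In the tagged set, APPPS1 minus WT called 1010 genes (684 higher, 326 lower, 110 of them predicted). The library labelled APPPS1_12m_Mxo4 replicate 56 had Cst7 at 10.9 CPM, whereas the other 3 of its group had 1650 to 2400 CPM. Cst7 rose by 6.04 ± 0.76 (adjusted p = 2.9e-06) over WT at 24.4 ± 11.6 CPM (n = 3), above the WT range in 3 of 4 libraries. Mamdc2 rose by 7.34 ± 1.02, Baiap2l2 by 7.26 ± 0.96, the growth factor Igf1 by 4.25 ± 0.56 and the microglial growth factor Csf1 by 2.63 ± 0.38. Apoe rose by 2.17 ± 0.41, Fabp5 by 3.48 ± 0.56, Lpl by 3.02 ± 0.50 and the lysosomal protease Ctsb by 1.22 ± 0.21. Hif1a rose by 1.75 ± 0.23, the transaminase Got1 by 1.53 ± 0.22, Psat1 by 2.47 ± 0.35, Il1b by 1.83 ± 0.37 and the antiviral gene Oasl2 by 1.77 ± 0.39. Arhgap15, a Rac inhibitor, fell (−1.52 ± 0.29, adjusted p = 0.00061). Disease-associated genes rose in 23 of 25 (25 over the list alone, 0.0416 with an estimated correlation), cholesterol synthesis in 8 (11; 0.0416) and glycolysis in 12 with 1 falling (14 and 1; 0.0416). Lysosome genes (14 up; 16 up and 2 down over the list alone; 0.1), ribosomal proteins (13; 20; 0.1), interferon genes (6; 15; 0.305) and MHC class I genes (4; 10; 0.129) passed with the preset correlation only. Border-associated macrophage markers, with 1 of 10 falling (median −0.84; 4.7e-05, and 0.309 with an estimated correlation), and astrocyte markers (−0.87; 0.00044 and 0.402) lay lower. The count was 1552 with second title number 1 and 0 with 2, where replicate 56 is the only APPPS1 library. Without replicate 56 it was 2509, and without replicate 57, 58, 59, 60 or 61 it was 587, 420, 597, 549 or 604.

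The transgene difference without Nlrp3, APPPS1_NLRP3 minus NLRP3, had 2 genes called at 4 months, both higher. Cst7 rose from 6.13 ± 0.741 to 91.4 ± 33.3 CPM (n = 4 each, 3.89 ± 0.63, adjusted p = 0.0032, and 0.0511 without replicate 15), and Lpl by 2.42 ± 0.45 (adjusted p = 0.025). Disease-associated genes had a median of 0.21 (2 up of 25, 6 over the list alone; 4.88e-07, and 0.503 with an estimated correlation). Immediate-early genes had 0 called and 12 lower over the list alone (−0.61; 2.15e-21 and 0.103). Erythroid markers lay lower, 4 of them over the list alone (−1.60; 0.000669 and 0.503). Lpl lost its call without replicate 11 (0.0501), 8 (0.0669), 9 (0.134), 12 (0.0994), 10 (0.256), 13 (0.0964) or 15 (0.16), and 1 gene was left without replicate 11, 13, 12 or 10 and 0 without replicate 15. By second title number, 0 and 5 genes were called, and 0 with the first title number as a further term.

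At 6 months interferon and cytokine genes were among the rises in APPPS1_NLRP3, and 1596 genes were called (1224 higher, 372 lower, 160 of them predicted). Cxcl10 rose from 23.4 ± 4.95 (n = 4) to 110 ± 20.7 CPM (n = 5), a difference of 2.23 ± 0.21 (adjusted p = 6e-10). Il1b rose by 2.43 ± 0.33 from 254 ± 72 to 1368 ± 304 CPM, Tnf by 1.61 ± 0.23, the prostaglandin enzyme Ptgs2 by 2.30 ± 0.33, the bacterial lipoprotein receptor Tlr2 by 1.55 ± 0.20 and the interleukin subunit Il12b by 5.33 ± 0.86. Cst7 rose by 6.60 ± 0.69, Clec7a by 4.24 ± 0.47, Lpl by 4.27 ± 0.47, Ch25h by 4.04 ± 0.51, Axl by 3.04 ± 0.40, the oxygen sensor Egln3 by 4.63 ± 0.53 and the collagen cross-linker Lox by 4.61 ± 0.64. Hif1a rose by 1.47 ± 0.20, Psat1 by 2.50 ± 0.30, B2m by 1.17 ± 0.20, Gusb by 1.13 ± 0.14 and Cdk1 by 1.51 ± 0.24. Sod3, an extracellular antioxidant enzyme, fell (−1.61 ± 0.40). In each of these genes all 5 APPPS1_NLRP3 libraries lay beyond the range of the 4 NLRP3 libraries. All 25 disease-associated genes rose (0.00342 with an estimated correlation), with 18 of 22 interferon genes (19 over the list alone, 0.0188), 15 of 21 NF-kB genes (17; 0.00342), 10 MHC class I genes (13; 0.0188), 8 inflammasome genes (10, with 1 falling; 0.0188) and all 20 ribosomal protein genes (0.0188). Astrocyte markers fell in 3 (7 over the list alone, −1.01, 0.000182 and 0.266) and endothelial markers in 2 (8; −0.95, 1.84e-05 and 0.213). The count was 591 and 811 by second title number, and 1017 without replicate 31.

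At 12 months APPPS1_NLRP3 minus NLRP3 called 1727 genes (1098 higher, 629 lower, 239 of them predicted), all within male libraries. Cst7 rose by 7.05 ± 0.73 (adjusted p = 1.4e-08) from 12.7 ± 5.04 to 1539 CPM (n = 4 each), Lox by 6.55 ± 0.79, Lpl by 5.20 ± 0.52, Ch25h by 4.53 ± 0.57 and Clec7a by 4.17 ± 0.48. The interferon-induced genes Oasl2 and Ifit3 rose by 2.32 ± 0.37 and 2.08 ± 0.36, the interleukin receptor Il1r1 by 1.49 ± 0.32, Apoe by 2.10 ± 0.36 and Hif1a by 1.88 ± 0.21. Gsdmd, whose product forms pores downstream of inflammasomes, fell (−0.48 ± 0.09), as did the inhibitory lectin Siglecg (−1.81 ± 0.31) and Crybb1 (−1.07 ± 0.25). All 25 disease-associated genes (0.00925 with an estimated correlation) and all 22 interferon genes (0.0183) rose. NF-kB genes rose in 3 of 21 (adjusted p = 0.297), and the inflammasome list split into 6 rises and 1 fall (0.3). Choroid plexus markers fell in 1 of 8 (median −1.28; 0.00985, and 0.446 with an estimated correlation). The count was 732 and 414 by second title number.

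With the tag, APPPS1_NLRP3 minus NLRP3 called 1021 genes (696 higher, 325 lower, 107 of them predicted; n = 3 each). Baiap2l2 rose by 8.59 ± 1.04, Gpnmb by 7.83 ± 1.27, Cst7 by 6.52 ± 0.79, Igf1 by 4.17 ± 0.57, Fabp5 by 4.20 ± 0.60 and Apoe by 2.77 ± 0.43. Cxcl10 rose by 1.49 ± 0.24, Il1b by 1.67 ± 0.39, Psat1 by 2.87 ± 0.37 and the glutamine carrier Slc1a5 by 1.61 ± 0.32. Ptger3 fell (−3.07 ± 0.66), as did Gimap6, a gene of lymphocyte survival (−1.26 ± 0.20). Disease-associated genes rose in 25 of 25 (0.00203 with an estimated correlation), interferon in 20 of 22 (22 over the list alone, 0.0135) and glycolysis in 13 (0.00203). Homeostatic genes fell in 5 of 20 (10; −0.33, 0.000419 and 0.345). No APPPS1_NLRP3_12m_Mxo4 library has second title number 1, and 962 genes were called with 2. Without replicate 51, 50 or 54 the count was 618, 606 or 581.

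**Figure D2:**
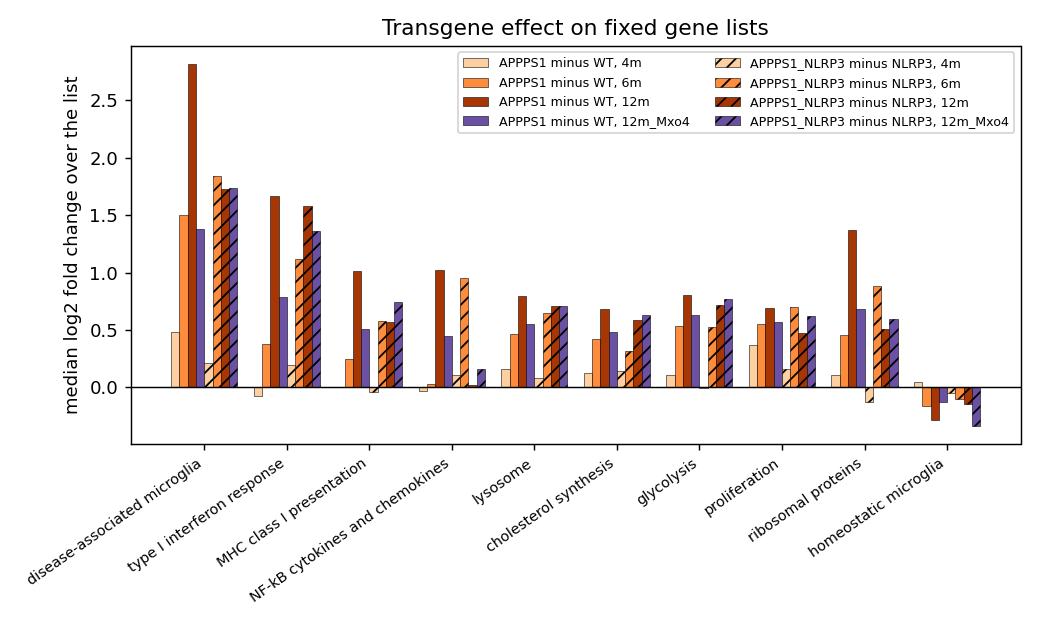
Median log2 difference of 10 gene lists (bars, from 0) for the transgene comparison at each age and with the tag, plain for APPPS1 minus WT and hatched for APPPS1_NLRP3 minus NLRP3. The disease-associated median reaches 2.82 in APPPS1 minus WT at 12 months and 1.73 without Nlrp3. The untagged 12-month libraries were all female with Nlrp3 and all male without it.

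Without any shared library, the transgene comparisons with and without Nlrp3 called many of the same genes. At 4 months the 2 genes shared were Cst7 and Lpl, where independent lists of these sizes would share 0.000503. At 6 months 309 rises and 45 falls were shared, against 25.3 and 3.6, at 12 months 826 and 297, against 122 and 43.8, and with the tag 443 and 113, against 24 and 5.33.

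Interactions asked whether the transgene difference depends on Nlrp3. At 6 months 3 genes were called, all higher without Nlrp3. Cxcl10 led at 1.80 ± 0.30 (adjusted p = 0.005, and 0.101 without replicate 22), with a WT mean of 34.1 ± 8.77, APPPS1 of 46.9 ± 9.68, NLRP3 of 23.4 ± 4.95 and APPPS1_NLRP3 of 110 ± 20.7 CPM. Rasgef1b, an exchange factor induced by Toll-like receptors, stood at 1.30 ± 0.25 (adjusted p = 0.021) and the non-coding RNA Snhg15 at 1.19 ± 0.22 (adjusted p = 0.021). Rasgef1b lost its call without replicate 23 (0.165), 30 (0.0958), 18 (0.0656), 32 (0.0952), 33 (0.0702), 22 (0.172) or 29 (0.0548), and Snhg15 without replicate 26 (0.0897), 23 (0.165), 30 (0.0958), 18 (0.0656), 32 (0.0642) or 22 (0.101). NF-kB cytokines had 0 of 21 called and 17 higher over the list alone (median 0.86; adjusted p = 0.00538 with an estimated correlation), and inflammasome genes 4 over the list alone (0.22, 0.0135). Immediate-early genes moved with them (0 called, 12 higher over the list alone; 0.84, 3.08e-15, and 0.127 with an estimated correlation). Neuron markers (−1.89, 0.179) and astrocyte markers (−1.15, 0.179) lay lower. With second title number 2, 1 gene was called. The count was 8 without replicate 25, 0 without replicate 22 and 1 without replicate 30, 23, 18 or 32. With the first title number as a further term no gene was called (0).

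At 12 months the cytokine interaction lay below 0, and no gene passed in edgeR (1961 at unadjusted p under 0.05, and 92 called with DESeq2). Without replicate 56 and the near-empty library, both of other groups, 26 passed. Without the tag, all 12-month libraries with Nlrp3 were female and all without it male. Dependence on Nlrp3 there cannot be told apart from dependence on sex, and a sex term cannot separate them. Il1b had the smallest adjusted p at −2.55 ± 0.48 (adjusted p = 0.06). It rose from 222 ± 70.8 to 1729 ± 464 CPM with Nlrp3, and was 788 ± 298 and 1047 ± 188 CPM without it. Il1b passed without replicate 49 (0.0439), 47 (0.00548), 37 (0.0105), 39 (0.028), 36 (0.0286) or 43 (0.0452). Ifitm2, an antiviral membrane gene, followed at −1.79 ± 0.38 (adjusted p = 0.06, but 0.0105, 0.0286 or 0.0452 without replicate 37, 36 or 43). NF-kB genes had 10 lower over the list alone (median −0.84; 1.89e-12, and 0.0653 with an estimated correlation), ribosomal proteins 20 (−0.85; 4.99e-20 and 0.141) and oxidative phosphorylation 10 (−0.45; 1.81e-10 and 0.159). Monocyte markers lay lower as well (−2.05; 0.00028 and 0.285), where APPPS1_12m replicate 38 carried most of the markers (5.11, against 2.19 to 2.78 in the rest of its group). By second title number, 0 and 63 genes were called. Without replicate 37 the count was 237, without replicate 36 it was 26, and without replicate 49, 43, 42, 47 or 39 it was 2, 8, 4, 3 or 4. No gene passed at 4 months (355 at unadjusted p under 0.05, and 1 with DESeq2), with Zkscan2, a zinc finger gene, at 1.49 ± 0.42. With the tag no gene passed either (802, and 1 with DESeq2), with the sulfate carrier Slc26a11 at 1.47 ± 0.39. By second title number, 0 and 0 genes were called at 4 months. Interferon genes in the tagged set had a median of 0.54 (3 higher over the list alone; 4.61e-11, and 0.601 with an estimated correlation), and of −0.023 with a sex term and without replicate 56.

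Between NLRP3 and WT few genes were called, Slc1a3 among them at every age. At 4 months 75 genes were called in NLRP3 minus WT (36 higher, 39 lower, 19 of them predicted). Nlrp3 fell from 83.7 ± 6.88 to 0.70 CPM (n = 4 each, −6.89 ± 0.37, adjusted p = 3e-19). Slc1a3, the glutamate carrier also called GLAST (ENSMUSG00000005360, chr15 8634124 to 8710764, − strand, 8 transcripts), rose from 323 ± 18.6 to 2382 ± 130 CPM (2.88 ± 0.41, adjusted p = 3.6e-05). Its neighbour Ranbp3l, a nuclear export gene (chr15 8967949 to 9067335, + strand), rose by 3.45 ± 0.50, the translation factor Paip1 by 2.78 ± 0.48 and the lysosomal sulfatase Sgsh by 1.53 ± 0.23. All 4 NLRP3 libraries lay beyond the WT range in each. Il1b rose by 1.49 ± 0.33 (adjusted p = 0.024), from 124 ± 27.9 to 350 ± 89.4 CPM, a call lost without replicate 1 (0.126), 8 (0.109), 4 (0.0827), 5 (0.0831) or 15 (0.0606). Glutamine and glutamate genes had 1 up, Slc1a3, and 1 down. NF-kB genes (median 0.34; 0.000106), MHC class II genes (0.76; 3.83e-05) and border-associated macrophage markers (0.66; 3.83e-05) were called together with the preset correlation, each at adjusted p = 0.498 with an estimated correlation. By second title number 8 and 6 genes were called. Without replicate 1, 4, 7, 5, 8, 10 or 15 the count was 42, 39, 43, 31, 45, 45 or 34, and 38 with the first title number as a further term.

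**Figure D3:**
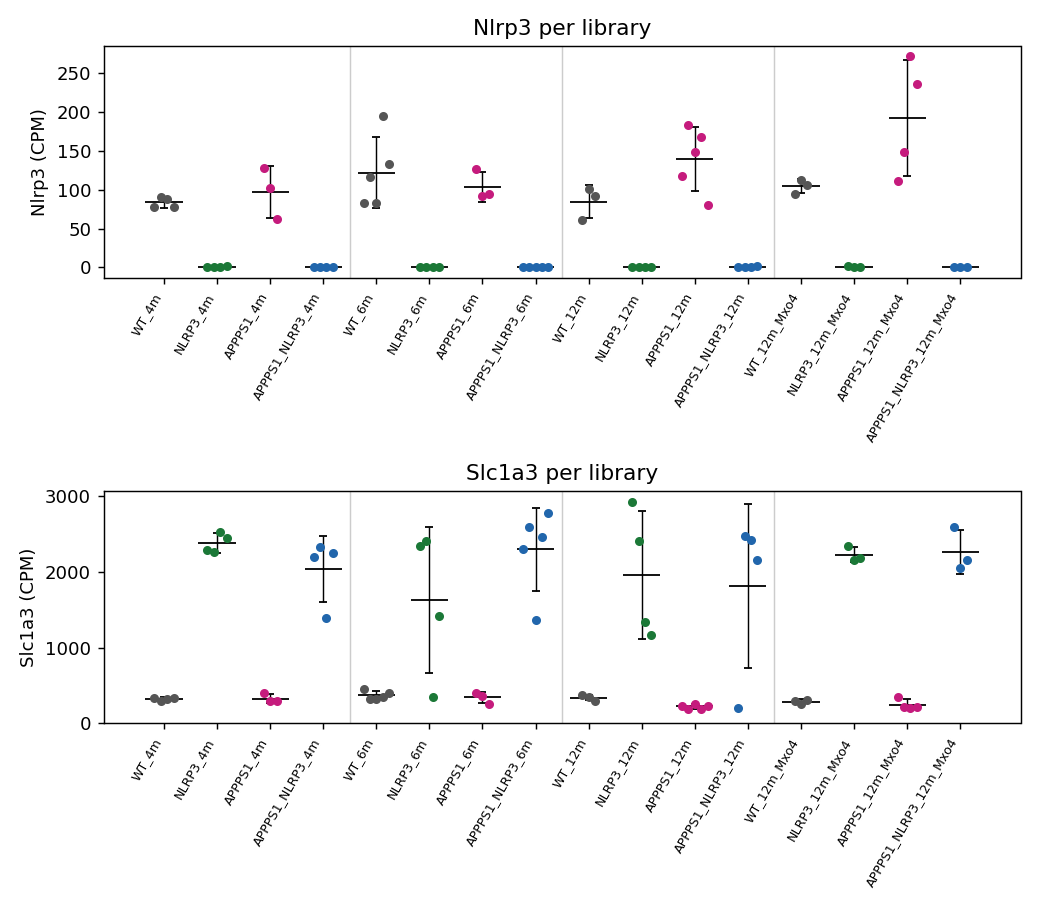
Nlrp3 and Slc1a3 levels in CPM (linear axes) for each library by group, with points for libraries and mean ± SD. Groups without Nlrp3 have Slc1a3 means from 1628 to 2382 CPM, and replicates 32 and 43 among them stand at 342 and 202 CPM.

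At 6 months NLRP3 minus WT called 88 genes (37 higher, 51 lower, 15 of them predicted). Slc1a3 rose by 2.14 ± 0.37 (adjusted p = 0.0015) in 3 of 4 libraries, and replicate 32 stayed at 342 CPM, inside the range of the libraries with intact Nlrp3 (192 to 459 CPM). The clock genes Per2 and Per3 rose by 1.78 ± 0.32 and 1.38 ± 0.24. Ranbp3l, at 2.39, lost its call without replicate 26 (0.0591). NF-kB genes lay lower (median −0.36; 5.2e-07, and 0.26 with an estimated correlation), as did interferon genes (−0.29; 9.72e-05 and 0.648), and choroid plexus markers lay higher (0.86; 0.00688 and 0.562). The count was 7 and 16 by second title number, and 31, 49, 56, 26, 48, 25, 50 or 32 without replicate 27, 26, 32, 33, 20, 19, 17 or 18. It was 14 with the first title number as a further term.

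At 12 months the comparison set 4 male NLRP3 libraries against 3 female WT libraries, and 292 genes were called (88 higher, 204 lower, 25 of them predicted). Slc1a3 rose by 2.55 ± 0.46 (adjusted p = 0.0016), Tnf, a cytokine of NF-kB signalling, by 1.58 ± 0.26 (126 ± 38.5 to 373 ± 127 CPM), and Il1b by 1.82 ± 0.37 (adjusted p = 0.0069, but 0.0513 without replicate 34 and 0.0957 without replicate 40). Ranbp3l rose by 2.99 ± 0.57 (0.0525 without replicate 40). The endothelial genes Adgrl4 (−2.68 ± 0.46) and Tmem252 (−3.10 ± 0.68) and the glucose carrier Slc2a1 (−1.16 ± 0.23) fell. Endothelial markers fell in 6 of 11 (11 over the list alone, median −1.54, 6.92e-13, and 0.181 with an estimated correlation). NF-kB genes had 1 riser of 21 (0.25; 0.00246 and 0.69), and ribosomal proteins 6 over the list alone (0.45; 1.11e-09 and 0.675). The count was 35 and 9 by second title number, and 592, 168, 124, 140 or 23 without replicate 42, 47, 45, 34 or 40. It was 140 with a sex term and 128 with the first title number as a further term. With the tag 19 genes were called (11 higher, 8 lower, 4 of them predicted; n = 3 each). Slc1a3 rose by 2.95 ± 0.48 (adjusted p = 0.00083) and Ranbp3l by 3.43 ± 0.59, and Fam219b, of unknown function, fell (−1.24 ± 0.20). Immediate-early genes lay higher (0.41; 0.000513 and 0.936 with an estimated correlation). Within second title number 1 and 2, 4 and 6 genes were called, and 8, 11, 10 or 12 without replicate 60, 61, 51 or 50.

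In mice with the transgenes, Slc1a3 and Ranbp3l were higher in the group without Nlrp3 as well. APPPS1_NLRP3 minus APPPS1 called 41 genes at 4 months (19 higher, 22 lower, 9 of them predicted). Slc1a3 rose by 2.65 ± 0.46 (adjusted p = 0.0015), Ranbp3l by 3.14 ± 0.56, Sgsh by 1.65 ± 0.26 and the G protein gene Gnb1 by 1.05 ± 0.17. The ribonuclease gene Rnaset2b fell (−2.00 ± 0.34). Border-associated macrophage markers had 7 higher over the list alone (median 1.10; 5.35e-12, and 0.222 with an estimated correlation), beside NF-kB genes with 3 (0.35; 6.08e-07 and 0.314). Split by second title number, 8 and 4 genes were called, and 27, 26, 22, 20 or 20 without replicate 11, 14, 13, 6 or 3. At 6 months 97 genes were called (59 higher, 38 lower, 18 of them predicted). Slc1a3 rose by 2.77 ± 0.44, Cxcl10 by 1.25 ± 0.22 (adjusted p = 0.0016, and 0.0611 without replicate 22) and Tnf by 1.13 ± 0.25 (adjusted p = 0.014, but 0.189 without replicate 23 and 0.0965 without replicate 22). The cilium gene Rpgrip1 fell (−1.90 ± 0.35). NF-kB genes rose in 2 of 21 (11 over the list alone, 0.48, 5.16e-11, and 0.0976 with an estimated correlation), with lysosome (4 over the list alone, 0.21, 0.189) and immediate-early genes (5; 0.55, 0.189). Within second title number 2, 19 genes were called, and 61, 59, 28, 41 or 29 without replicate 31, 30, 23, 24 or 22. With a sex term 64 were called, and 48 with the first title number as a further term.

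At 12 months the comparison set 4 male APPPS1_NLRP3 libraries against 5 female APPPS1 libraries and called 1134 genes (479 higher, 655 lower, 155 of them predicted). Il6 fell (−1.50 ± 0.24, adjusted p = 0.00012), from 46.8 ± 34.4 to 16.2 ± 2.41 CPM, and the stress factor Atf3 fell (−1.08 ± 0.25). Mamdc2 fell (−4.89 ± 0.75, adjusted p = 6.8e-05), from 106 ± 54.3 to 3.41 ± 2.32 CPM. Slc1a3 rose by 3.03 ± 0.38 in 3 of 4 libraries, and replicate 43 stayed at 202 CPM. The endothelial genes Ly6c1 (−1.77 ± 0.38) and Itm2a (−1.94 ± 0.43) fell, and endothelial markers fell in 6 of 11 (11 over the list alone, −1.62, 2.05e-10, and 0.134 with an estimated correlation). NF-kB genes fell in 6 of 21 (10; −0.56, 8.66e-06 and 0.194), immediate-early genes in 6 of 22 (15; −0.67, 4.02e-11 and 0.194), inflammasome genes in 2 (7, with 2 rising; −0.21, 0.000344 and 0.0946) and T and NK cell markers in 3 of 8 (−1.68, 0.00378 and 0.194). Neuron markers rose in 1 of 11 (10; 2.22, 1.19e-06 and 0.206). The disease-associated list had 0 called (−0.41, 0.000344 and 0.57). The count was 32 and 2512 by second title number, and 394, 255, 519, 2299 or 536 without replicate 49, 44, 35, 37 or 41. It was 164 with a sex term and 469 with the first title number as a further term.

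With the tag APPPS1_NLRP3 minus APPPS1 called 57 genes (24 higher, 33 lower, 10 of them predicted). Slc1a3 rose by 3.19 ± 0.44 (adjusted p = 1.5e-05), the magnesium channel Trpm6 by 3.80 ± 0.68, Sgsh by 2.13 ± 0.26, its neighbour Slc26a11 by 1.59 ± 0.27 and Card14, an NF-kB activator, by 2.17 ± 0.35. Cxcl10 rose by 1.53 ± 0.23 (adjusted p = 9.5e-05), from 43.1 ± 10 (n = 4) to 131 ± 23.8 CPM (n = 3). Mamdc2 fell (−4.35 ± 0.87, adjusted p = 0.0073, but 0.0536 without replicate 54 and 0.13 without replicate 52). Complement genes fell in 2 of 16, and the list did not pass (adjusted p = 0.612). Interferon genes had 1 riser (median 0.26; 7.6e-08, and 0.669 with an estimated correlation), and without replicate 56 their median was −0.046. With second title number 2, 795 genes were called, but there replicate 56 is the only APPPS1 library. Without replicate 54, 52, 53 or 58 the count was 28, 29, 26 or 37. The 2 comparisons of Nlrp3 loss share no library and called 15 of the same rises and 12 of the same falls at 4 months, against 0.0344 and 0.0432 for independent lists. At 6 months they shared 15 rises of 37 and 59, and 11 falls of 51 and 38. At 12 months they shared 21 rises of 88 and 479, and 88 falls of 204 and 655, against 2.12 and 6.73, but there both set male against female libraries. With the tag they shared 6 rises of 11 and 24, and 3 falls of 8 and 33. Of 55 genes besides Nlrp3 called in at least 3 of the 8 comparisons of Nlrp3 loss in 1 direction, 35 had another of them 0.1 to 5 Mb away, as Slc1a3 and Ranbp3l do.

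In 12m minus 4m, 5 genes were called in WT, all higher, 2 of them predicted, and 1 with the first title number as a further term. Ildr2, a gene of lipid handling and immune restraint (chr1 166254139 to 166316823, + strand), rose from 17.6 ± 4.61 (n = 4) to 39.4 ± 8.28 CPM (n = 3, 1.19 ± 0.17, adjusted p = 0.00016). The potassium channel Kcnj12 (chr11 61022564 to 61071131, + strand) rose by 1.70 ± 0.33 (adjusted p = 0.035), a call lost without replicate 1 (0.171), 4 (0.28), 34 (0.215) or 40 (0.149). The peptidase gene Naalad2 rose by 1.10 ± 0.22 (adjusted p = 0.035), lost without replicate 1 (0.113), 4 (0.226), 34 (0.452), 7 (0.112), 40 (0.274) or 5 (0.172). T and NK cell markers lay lower (median −1.10; 0.000426, and 0.312 with an estimated correlation). Split by second title number, 1 and 1 gene were called, and 2, 1, 3 or 1 without replicate 1, 4, 7 or 34. In NLRP3, Ildr2 rose by 1.73 ± 0.17 (adjusted p = 1.2e-09), Kcnj12 by 2.27 ± 0.32 and Zkscan2 by 2.24 ± 0.29 among 83 calls (41 higher, 42 lower, 7 of them predicted). Tnf rose by 1.20 ± 0.23 (adjusted p = 0.0071), a call lost without replicate 10 (0.0501). Immediate-early genes fell in 1 of 22 (15 over the list alone, −0.70, 1.89e-12, and 0.532 with an estimated correlation). The NLRP3 groups were female at 4 months and male at 12 months. Their count was 6 and 7 by second title number, and 363, 24, 55, 25, 228, 37, 24 or 19 without replicate 42, 47, 48, 45, 8, 12, 10 or 15. It was 27 with a sex term and 36 with the first title number as a further term.

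With the transgenes, age changed far more genes. APPPS1 had 4430 calls (2578 higher, 1852 lower, 651 of them predicted). Dkk2 rose by 6.07 ± 0.95, the heparanase gene Hpse by 4.94 ± 0.66, Il1b by 3.25 ± 0.39 (adjusted p = 8.2e-08), Apoe by 2.95 ± 0.41, the complement gene C3 by 3.10 ± 0.51 and the ferritin gene Fth1 by 1.41 ± 0.17. Ptger3 fell (−3.06 ± 0.55), as did the orphan receptor Gpr165 (−2.82 ± 0.39), the semaphorin Sema4b (−2.17 ± 0.25) and Tmem119 (−0.72 ± 0.17). All 25 disease-associated genes (0.0235 with an estimated correlation) and all 22 interferon genes (0.0235) rose. Neutrophil markers rose in 5 of 11 (9 over the list alone, 2.56, 0.046 and 0.69), and monocyte markers in 5 of 10 (1.96, 0.0227 and 0.418). Both rises rested mostly on replicate 38, whose mean log2 levels were 6.99 and 5.11, against 2.23 to 3.2 and 2.19 to 2.78 in the other 4 libraries. APPPS1_NLRP3 had 2402 calls (1441 higher, 961 lower, 289 of them predicted), with female libraries at 4 and male ones at 12 months. The osteopontin gene Spp1 rose by 4.56 ± 0.64, Cst7 by 4.08 ± 0.61 and Il1b by 1.34 ± 0.33 (adjusted p = 0.0041), and the endothelial gene Pecam1 fell (−1.75 ± 0.26). All 25 disease-associated genes rose (0.0271). APPPS1 minus WT of this age difference called 978 genes (736 higher, 242 lower, 99 of them predicted). The receptor Cd200r4 led at 4.49 ± 0.77, with Igf1 at 3.99 ± 0.71 (adjusted p = 0.0019), Apoe at 2.90 ± 0.55, Ifitm3 at 2.43 ± 0.42, Hif1a at 1.75 ± 0.31 and Ldha at 1.27 ± 0.21. Disease-associated genes passed in 22 of 25 (25 over the list alone, 0.0184) and interferon genes in 17 of 22 (22; 0.0184). Within second title number 1 and 2, 1 and 2, APPPS1 had 1485 and 3495 calls, APPPS1_NLRP3 857 and 1096, and the difference 7 and 1513. The last was 565, 644, 1692 or 638 without replicate 3, 2, 37 or 39, and 132 with the first title number as a further term.

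In Mxo4 minus untagged at 12 months, WT had 33 calls (12 higher, 21 lower, 7 of them predicted), and no named gene held in every leave-out. The endothelial genes Nostrin (−2.03 ± 0.40, adjusted p = 0.033) and Emcn (−2.14 ± 0.44) fell, and the lysosomal reductase Ifi30 rose by 0.68. Nostrin lost its call without replicate 60 (0.139), 61 (0.126) or 34 (0.0628), Emcn without these or 40 (0.0568) or 62 (0.0759), and Ifi30 without replicate 60 (0.128), 61 (0.126), 40 (0.0807), 62 (0.213) or 39 (0.23). Endothelial markers had 10 lower over the list alone (median −1.24; 9.3e-11, and 0.112 with an estimated correlation) and neuron markers 7 (−2.69; 8.4e-07 and 0.322). The count was 0 and 5 by second title number, and 0, 2, 11, 8 or 3 without replicate 60, 61, 62, 34 or 39. It was 6 with a sex term, and 6 with the first title number as a further term. NLRP3 had 1316 calls (410 higher, 906 lower, 159 of them predicted). The signalling regulator Rgs1 rose from 532 ± 140 (n = 4) to 2261 ± 512 CPM (n = 3, 2.00 ± 0.31, adjusted p = 0.00016), the immediate-early gene Fos (chr12 85473890 to 85477273, + strand) by 1.88 ± 0.42, and the transcription factors Klf4 by 1.73 ± 0.33, Klf2 by 1.52 ± 0.30 and Klf6 by 1.40 ± 0.23. Immediate-early genes rose in 14 of 22 (17; 1.02, 5.46e-19 and 0.168), and neuron markers fell in 8 of 11 (11; −4.01, 2.6e-10 and 0.202). Split by second title number, 1 and 1 gene were called, and 2337, 129, 224, 696 or 172 without replicate 42, 47, 51, 55 or 50. With the first title number as a further term 628 were called.

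APPPS1 had 1268 calls for the tag (536 higher, 732 lower, 189 of them predicted). The growth factor Hbegf rose by 3.22 ± 0.58 (adjusted p = 0.0012). The pericyte genes Vtn (−2.73 ± 0.43), Rgs5 (−2.70 ± 0.39) and Pdgfrb (−2.11 ± 0.45) fell, with endothelial Emcn (−2.33), the interferon genes Cxcl10 (−1.18 ± 0.20) and Ifit1 (−1.48 ± 0.27), the inflammasome adaptor Pycard (−0.70 ± 0.15) and Ldha (−0.69 ± 0.14). Endothelial markers fell in 8 of 11 (9 over the list alone, −1.43, 3.77e-09, and 0.246 with an estimated correlation), interferon genes in 5 of 22 (18; −0.77, 1.32e-12 and 0.246) and monocyte markers in 4 of 10 (−1.36, 0.00871 and 0.37). The tagged group includes replicate 56, which lacked the transgene response. The mean log2 level of interferon genes was 4.68 ± 0.84 in the tagged group (n = 4) and 5.57 ± 0.27 in the untagged one (n = 5). Without replicate 56 the falls of the interferon list, Cxcl10, Ifit1 and Ldha were smaller, and that of Pycard was not. The monocyte fall rested mostly on untagged replicate 38 (5.11, against 2.19 to 2.78 in the other 4 untagged libraries). Within second title number 1 and 2, 142 and 3958 genes were called, but with 2 replicate 56 is the only tagged APPPS1 library. The count was 845, 380, 2550, 2113, 354, 569 or 528 without replicate 38, 35, 37, 36, 41, 56 or 59. The untagged libraries were female and 3 of the 4 tagged ones male, and 267 genes were called with a sex term and 204 with the first title number as a further term. APPPS1_NLRP3 had 182 calls (95 higher, 87 lower, 30 of them predicted). The linker histone Hist1h1d rose by 2.59 ± 0.36 (adjusted p = 4.5e-05), and Fosb from 80 ± 38.5 (n = 4) to 224 ± 19.8 CPM (n = 3, 1.71 ± 0.32). Immediate-early genes rose in 12 of 22 (17; 1.12, 0.0182 with an estimated correlation), and neuron markers fell in 2 (11; −3.55, 1.97e-11 and 0.0908). With second title number 2, 110 genes were called, and 75, 23, 404, 22, 24 or 25 were called without replicate 49, 44, 43, 54, 52 or 53. A sex term left 64 and the first title number as a further term 61. APPPS1 minus WT of the tag difference called 3 genes (2 higher, 1 lower, 1 of them predicted), with Ifi30 at −1.01 ± 0.20 (adjusted p = 0.049), which lost its call without replicate 57 (0.053), 38 (0.0927), 61 (0.0718), 58 (0.051), 40 (0.0906), 62 (0.386), 56 (0.0741), 39 (0.366) or 41 (0.156). Inflammasome genes had 4 lower over the list alone (−0.38, 0.0378 with an estimated correlation), and interferon genes 9 (−0.86, 0.125), but both medians lay closer to 0 without replicate 56. Split by second title number, 1 and 1296 genes were called, the latter with replicate 56 as the only tagged APPPS1 library. The count was 38 without replicate 37, 14 without replicate 36, and 6, 5, 7, 1, 1, 5, 0, 0 or 0 without replicate 57, 58, 59, 38, 41, 34, 40, 39 or 62.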

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

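The regroupings of libraries and the tests of sex, neuronal RNA and endothelial RNA were set before their results were seen, and all other tests in this part were chosen only after the result was seen.

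More genes were called between APPPS1_NLRP3 and APPPS1 at 12 months without the tag (1134) than with it (57), and the untagged groups also differ in sex. In 6 groups with both sexes, the 1076 autosomal genes called had a sign-aligned male minus female median of 0.032, against 0.911 here. None was untagged at 12m, so this argued only against a sex effect common to groups. Endothelial RNA stays open for part of the falls (0.191 of 649 genes followed its markers, against 0.023 of genes not called). The 714 calls without the 3 shallowest libraries argued against depth as the whole cause. RNA from neurons cannot be told apart from the genotype for the rises, because 0.448 of 478 genes followed the neuron markers (0.049 of genes not called) and the groups themselves differ in them. Loss of Nlrp3 or sex in these groups stays open for the rest. A sex term left 164 calls (aligned median of the same genes 0.841).

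The library labelled APPPS1_12m_Mxo4 replicate 56 lacked the transgene response. On an axis over 3590 genes from WT at 0 to the other 3 tagged APPPS1 libraries at 1, it lay at −0.059, as a mouse without the transgenes could. Among libraries that set neither end of the axis, those of tagged NLRP3 lay between 0.007 and 0.13 and those of tagged APPPS1_NLRP3 between 0.873 and 1.009. The axis shows the missing response and not that the transgenes are absent, since APPPS1_4m libraries lay between −0.215 and −0.009. Prnp was 30.1 CPM, within tagged WT (25.1 to 34.5) and below the other 3 (37.6 to 44.2), but without the tag APPPS1_12m replicate 41 at 36.7 CPM also lay within WT_12m (26 to 44.6). A swap was argued against, since 0 libraries labelled as without transgenes lay over 0.5 on the axis, and low depth too, at 20454324 counts. No biological explanation was tested, and a wrong label or a carrier with no response stays open.

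Of 55 genes besides Nlrp3 called in at least 3 of the 8 comparisons of Nlrp3 loss, always in 1 direction, 0.636 had another of them 0.1 to 5 Mb away on the chromosome, as Slc1a3 and Ranbp3l do. Random genes had a share of 0.236 at the median, and 0 of 10000 sets reached it, which is consistent with stretches of another strain's genome in the knockout line. A single stretch around Nlrp3 was argued against, since 0 of the genes lay within 10 Mb of it. Loss of Nlrp3 as the sole cause for Slc1a3 was argued against, as 2 of 31 libraries without Nlrp3 had Slc1a3 within the range of intact libraries (192 to 459 CPM), and these also had low Ranbp3l (2.55 and 2.41 CPM). Genotypes at these stretches were not analysed here.

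Each comparison was repeated with its libraries regrouped in up to 25 ways, the real one included. Groupings with as many calls as the real one are counted. Only the real grouping reached its count (1 of 25) in the following (real count against highest other). The 24 comparisons between 2 groups were not corrected for their number, so 1 of 25 alone does not exclude chance. APPPS1 minus WT had 602 against 168 at 6m and 3590 against 1795 at 12m. NLRP3 minus WT had 75 against 0 at 4m and 88 against 5 at 6m, and APPPS1_NLRP3 minus APPPS1 had 41 against 4 and 97 against 18. APPPS1_NLRP3 minus NLRP3 had 2 against 0, 1596 against 1168 and 1727 against 968 at 4m, 6m and 12m. 12m minus 4m had 5 against 2 in WT, 4430 against 4250 in APPPS1 and 2402 against 29 in APPPS1_NLRP3, and Mxo4 minus untagged in NLRP3 had 1316 against 655. Regrouping left chance open for other comparisons between 2 groups. At 2 groupings of 25 stood APPPS1 minus WT at 4m (5 against 5), NLRP3 minus WT at 12m (292 against 501), APPPS1_NLRP3 minus APPPS1 at 12m (1134 against 2312), 12m minus 4m in NLRP3 (83 against 303) and Mxo4 minus untagged in APPPS1_NLRP3 (182 against 323). At 3 stood APPPS1_NLRP3 minus APPPS1 with the tag (57 against 75) and Mxo4 minus untagged in APPPS1 (1268 against 2530). At 4 stood APPPS1 minus WT with the tag (1010 against 2906). A regrouping of 2 groups with several times the real count, as in 12m minus 4m of NLRP3 or APPPS1 minus WT with the tag, points to a structure of the samples besides their labels. For comparisons between 4 groups these splits decide nothing. They also move other differences, such as that of the transgenes, into the one tested, and a real count of 0 is always reached. The interactions had 25 of 25 at 4m (0 against 0), 12m (0 against 3360) and with the tag (0 against 1327). At 6m they had 2 (3 against 285). APPPS1 minus WT had 2 for the age difference (978 against 2065) and 11 for the tag difference (3 against 621). Only 10 regroupings exist with the tag for NLRP3 minus WT (19 against 0) and APPPS1_NLRP3 minus NLRP3 (1021 against 0). For these and Mxo4 minus untagged in WT (33 against 2), 1 of 10 alone cannot exclude chance. Rises shared with the tag by transgene comparisons (443, against 24) or Nlrp3 loss (6, against 0.0133) cannot either, as independent genes are assumed.

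Effects that differ between groups were tested directly. The transgene effect differed by Nlrp3 at 6m in 3 genes, APPPS1 minus WT differed between ages in 978 genes, and the tag effect differed between APPPS1 and WT in 3 genes.

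Of 211 groups of values tested for a sample far from the others, 22 had such a sample, where chance gives about 1 in 20. The total count of APPPS1_12m_Mxo4 replicate 57 was 11769573, against 20454324 to 20912997 in the others. Nlrp3 in APPPS1_NLRP3_12m replicate 49 was 2.27 CPM (others 0.492 to 0.758). App was 171 CPM in APPPS1_12m replicate 41 (278 to 304), 347 in APPPS1_NLRP3_12m replicate 46 (271 to 281) and 325 in NLRP3_12m replicate 45 (231 to 244). Prnp was 53.2 CPM in WT_6m replicate 16 (39.2 to 43.1), and Thy1 0.934 CPM in WT_6m replicate 19 (0 to 0.237). Cst7 was 1100 CPM in APPPS1_NLRP3_12m replicate 49 (1650 to 1750). Slc1a3 was 350 CPM in the library labelled APPPS1_12m_Mxo4 replicate 56 (198 to 214), 202 in APPPS1_NLRP3_12m replicate 43 (2160 to 2480) and 1390 in APPPS1_NLRP3_4m replicate 13 (2200 to 2330). The rest are mean log2 levels of marker lists. Immediate-early genes stood at 8.57 in APPPS1_NLRP3_12m replicate 44 (9.03 to 9.1), neuron markers at 2.03 in APPPS1_NLRP3_4m replicate 9 (3.87 to 4.01) and endothelial markers at 7.25 in NLRP3_6m replicate 27 (6.39 to 6.46). APPPS1_12m replicate 38 stood at 5.11 for monocyte markers (2.19 to 2.78), 6.99 for neutrophil markers (2.23 to 3.2) and 3.77 for B cell markers (3.29 to 3.41). Border-associated macrophage markers stood at 3.9 in APPPS1_12m replicate 36 (4.7 to 5.01). WT_4m replicate 4 stood at 4.61 for border-associated macrophage (5.32 to 5.41), 2.39 for T and NK cell (1.34 to 1.5) and 2.39 for erythroid markers (4.07 to 4.15), and WT_6m replicate 19 at 3.18 for B cell markers (3.72 to 3.82).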

How the results depend on the processing

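The counts of called genes depend on the model, the filter and single libraries, and those of the small comparisons most of all. Groups held 3 to 5 libraries, sex was not balanced at 6 or 12 months, and the library labelled APPPS1_12m_Mxo4 replicate 56 lacks the transgene response. Of 1103 calls of named genes, 563 held in every setting and in every leave-out. The cause of each change was not tested, apart from those set by construction, such as fewer libraries in a leave-out or more genes to adjust for without the filter. Signs of values that passed in no setting are not listed. Every leave-out of APPPS1 minus WT at 12m (2610 to 4591 calls), APPPS1_NLRP3 minus NLRP3 at 12m (1169 to 1859), 12m minus 4m in APPPS1 (3080 to 5362) and in APPPS1_NLRP3 (1715 to 2062) moved the count by less than 1.5 times. Unless a gene or list is named, values are counts of called genes that moved by more than 1.5 times or to or from 0.

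Without the low-count filter, APPPS1 minus WT had 1 call at 4m and 396 at 6m, and NLRP3 minus WT had 43, 47 and 129 at 4m, 6m and 12m. APPPS1_NLRP3 minus APPPS1 had 64, 572 and 36 at 6m, 12m and with the tag. Between 12m and 4m there was 1 call in WT and 47 in NLRP3, and Mxo4 minus untagged had 4, 840, 654 and 62 in WT, NLRP3, APPPS1 and APPPS1_NLRP3.

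With the first title number as a further term, APPPS1 minus WT had 2, 119 and 2243 calls at 4m, 6m and 12m, and NLRP3 minus WT had 38, 14 and 128. APPPS1_NLRP3 minus APPPS1 had 48 at 6m and 469 at 12m, and APPPS1_NLRP3 minus NLRP3 had 0 at 4m. The interaction at 6m had 0. 12m minus 4m had 1 in WT and 36 in NLRP3, and Mxo4 minus untagged had 6, 628, 204 and 61 in WT, NLRP3, APPPS1 and APPPS1_NLRP3. APPPS1 minus WT of the age difference had 132 and of the tag difference 5. Gh and Prl in APPPS1 minus WT at 6m turned to fitted values of −2.67 and −2.293, which are no measure of size with WT at the floor, and the median of MHC class II genes in the interaction at 4m to 0.048.

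DESeq2 called more genes. NLRP3 minus WT had 141, 152, 461 and 41 calls at 4m, 6m, 12m and with the tag, and APPPS1_NLRP3 minus APPPS1 had 69 at 4m and 88 with the tag. The interactions had 1, 5, 92 and 1 at 4m, 6m, 12m and with the tag. The age comparison 12m minus 4m had 15 in WT and 167 in NLRP3, Mxo4 minus untagged had 216 in WT and 521 in APPPS1_NLRP3, and APPPS1 minus WT of the tag difference had 18. The median of homeostatic genes in the interaction at 6m was −0.017.

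DESeq2 without the near-empty library had 1043 calls in APPPS1 minus WT at 6m, and 174, 225, 636 and 54 in NLRP3 minus WT at 4m, 6m, 12m and with the tag. APPPS1_NLRP3 minus APPPS1 had 91, 156, 1891 and 130, and APPPS1_NLRP3 minus NLRP3 had 6 at 4m. The interactions had 2, 30 and 150 at 4m, 6m and 12m. 12m minus 4m had 19 in WT and 295 in NLRP3, and Mxo4 minus untagged had 320, 2108 and 706 in WT, APPPS1 and APPPS1_NLRP3. APPPS1 minus WT of the age difference had 1522 and of the tag difference 35. The homeostatic median in the interaction at 6m was −0.027.

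RLE size factors gave 1 call in the interaction at 6m and 1 in APPPS1 minus WT of the tag difference. RLE without the near-empty library gave 13 in Mxo4 minus untagged in WT and 1 in that tag difference, and a homeostatic median of −0.027 in the interaction at 6m. Without the second title number, APPPS1_NLRP3 minus APPPS1 at 12m had 754 calls, the interaction at 12m 3, 12m minus 4m 3 in WT and 55 in NLRP3, and Mxo4 minus untagged 7 in WT and 277 in APPPS1_NLRP3. Without the 3 shallowest libraries, NLRP3 minus WT at 12m had 158 calls and APPPS1_NLRP3 minus APPPS1 at 12m 714. 12m minus 4m had 8 in WT and 44 in NLRP3, Mxo4 minus untagged 458 in APPPS1 and 290 in APPPS1_NLRP3, and the tag difference 1. The homeostatic median in the interaction at 6m was then 0.

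With a sex term, NLRP3 minus WT at 12m had 140 calls, and APPPS1_NLRP3 minus APPPS1 had 64 at 6m and 164 at 12m. For 12m minus 4m, NLRP3 had 27, Mxo4 minus untagged had 6, 267 and 64 in WT, APPPS1 and APPPS1_NLRP3, and the tag difference had 1. The Y-linked gene Kdm5d in 12m minus 4m of NLRP3, at the floor at 4m, turned to a fitted −0.16. Interferon medians turned to 0.23 in APPPS1_NLRP3 minus APPPS1 at 12m and to 0.13 in 12m minus 4m of NLRP3. The homeostatic median in the interaction at 6m turned to −0.02, and that of disease-associated genes in Mxo4 minus untagged of APPPS1_NLRP3 to −0.079.

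Without the library labelled APPPS1_12m_Mxo4 replicate 56 and the near-empty library, APPPS1 minus WT had 18 calls at 4m and 2508 with the tag, APPPS1_NLRP3 minus NLRP3 had 8 at 4m, and the interactions had 6 at 6m and 26 at 12m. 12m minus 4m had 10 in WT and 126 in NLRP3, Mxo4 minus untagged had 57 in WT and 581 in APPPS1, and the tag difference had 1. Medians of APPPS1_NLRP3 minus APPPS1 with the tag turned to −0.244 for disease-associated, −0.049 for interferon, 0 for NF-kB, −0.021 for lysosome, −0.003 for lipid transport and −0.096 for proliferation genes. Medians of the interaction with the tag turned to −0.102 for disease-associated, −0.049 for lysosome and 0 for glycolysis genes.

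With the sex term and without that replicate 56, APPPS1 minus WT had 19 calls at 4m and 2562 with the tag, NLRP3 minus WT 149 at 12m, APPPS1_NLRP3 minus APPPS1 184 at 12m and APPPS1_NLRP3 minus NLRP3 9 at 4m. The interactions had 10 at 6m and 26 at 12m, 12m minus 4m had 10 in WT and 45 in NLRP3, and Mxo4 minus untagged had 55, 409 and 81 in WT, APPPS1 and APPPS1_NLRP3. The fitted value of Kdm5d in 12m minus 4m of NLRP3 was −0.19. Interferon medians were 0.11 in APPPS1_NLRP3 minus APPPS1 at 12m and 0.057 in 12m minus 4m of NLRP3. Medians of APPPS1_NLRP3 minus APPPS1 with the tag were −0.33 for disease-associated, −0.12 for interferon, −0.036 for NF-kB, −0.052 for lysosome, −0.013 for lipid transport, −0.01 for glycolysis and −0.123 for proliferation genes. In the interaction with the tag they were −0.253 for disease-associated, −0.023 for interferon, −0.116 for lysosome and −0.043 for glycolysis genes, and in the interaction at 6m −0.009 for homeostatic genes. In Mxo4 minus untagged they were 0.131 for disease-associated, 0.033 for MHC class I and 0.022 for NF-kB genes in APPPS1, and −0.069 for disease-associated genes in APPPS1_NLRP3.

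With an estimated correlation, 71 list tests passed, against 411 with the preset one.

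Leaving out 1 library at a time moved most counts, and the lowest and highest are given with the replicate left out. APPPS1 minus WT ran from 1 (replicate 1) to 5 (2) at 4m, from 239 (24) to 605 (21) at 6m and from 420 (58) to 2509 (56) with the tag. NLRP3 minus WT ran from 31 (5) to 57 (12), 25 (19) to 73 (16), 23 (40) to 592 (42) and 8 (60) to 19 (55) at 4m, 6m, 12m and with the tag. APPPS1_NLRP3 minus APPPS1 ran from 20 (6) to 32 (2), 28 (23) to 85 (28), 255 (44) to 2299 (37) and 26 (53) to 65 (56). APPPS1_NLRP3 minus NLRP3 ran from 0 (15) to 2 (8) at 4m, 1017 (31) to 2004 (29) at 6m and 581 (54) to 856 (52) with the tag. The interaction ran from 0 (22) to 8 (25) at 6m and 0 (38) to 237 (37) at 12m. 12m minus 4m ran from 1 (4) to 6 (39) in WT and 19 (15) to 363 (42) in NLRP3. Mxo4 minus untagged ran from 0 (60) to 42 (40), 129 (47) to 2337 (42), 354 (41) to 2550 (37) and 22 (54) to 404 (43) in WT, NLRP3, APPPS1 and APPPS1_NLRP3. APPPS1 minus WT ran from 565 (3) to 1692 (37) for the age difference and 0 (40) to 38 (37) for the tag difference. S100a6, a calcium-binding gene, ran from −0.091 (38) to 2.249 (36) in 12m minus 4m of APPPS1, and from −2.343 (56) to 0.224 (38) in Mxo4 minus untagged of APPPS1. Monocyte medians ran from −0.21 (38) to 1.84 (36) in APPPS1 minus WT at 12m and from −0.051 (38) to 2.016 (36) in its age difference. In APPPS1_NLRP3 minus APPPS1 with the tag, medians without replicate 56 were −0.243 for disease-associated, −0.046 for interferon, −0.035 for lysosome, −0.001 for lipid transport and −0.095 for proliferation genes. Their highest values were 0.28 (58), 0.59 (58), 0.23 (58), 0.28 (52) and 0.23 (58), and MHC class II ran from −0.18 (53) to 0.69 (59). In the interaction with the tag, medians without replicate 56 were −0.123 for disease-associated, −0.058 for lysosome and −0.005 for glycolysis genes, and the highest were 0.404 (57), 0.24 (58) and 0.23 (58). Immediate-early medians ran from −0.097 (6) to 0.64 (2) in 12m minus 4m of APPPS1, and MHC class II medians from −0.03 (62) to 0.52 (39) in Mxo4 minus untagged of WT.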

Other observations

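The comparisons in this part were set beforehand, and Prnp was in the fixed set. Which genes to show here was chosen after the values were seen, from the same fit. Leave-outs are not given for them here. Ildr2 rose between 4 and 12 months in every genotype, from 11.2 ± 2.69 to 38.4 ± 2.54 CPM in NLRP3 (n = 4 each), from 15.9 ± 2.51 (n = 3) to 48.9 ± 11.8 CPM (n = 5) in APPPS1 and from 13.8 ± 2.44 to 52.6 ± 4.90 CPM (n = 4 each) in APPPS1_NLRP3. The differences were 1.73 ± 0.17, 1.63 ± 0.18 and 1.92 ± 0.17, each past the threshold. At 6 months it already stood at 32.2 ± 3.72 CPM in WT (n = 5). Kcnj12 rose in APPPS1 (1.38 ± 0.34) and APPPS1_NLRP3 (1.91 ± 0.31) as well. The groups without Nlrp3 were female at 4 and male at 12 months. The clock genes Per2 and Per3 passed without Nlrp3 at 6 months only, and a difference between ages was not tested for them. Per2 was at 24.1 ± 4.90 CPM in NLRP3 (n = 4) against 6.90 ± 2.44 in WT (n = 5), and at 15.1 ± 3.38 in APPPS1_NLRP3 (n = 5) against 4.75 ± 0.575 in APPPS1 (n = 3). Per3 rose by 1.38 ± 0.24 and 1.26 ± 0.27 in these comparisons. The labels give no hour of collection, and the time of day was not analysed here.

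Il1a, which encodes interleukin-1 alpha and lies beside Il1b on chr2, rose without Nlrp3 in untransgenic cells at 4 months (0.92 ± 0.22, adjusted p = 0.0392) and at 12 months (1.08 ± 0.24, adjusted p = 0.014). At 6 months Il1a rose without Nlrp3 in cells with the transgenes, from 990 to 1882 CPM. The growth factor gene Igf1 rose from 8.48 CPM in WT (n = 3) to 233 CPM in APPPS1 (n = 5) at 12 months, and Itgax, the integrin CD11c, from 13.7 to 211 CPM. Spp1 rose from 51.9 to 654 CPM in the same comparison, and from 17.6 to 570 CPM without Nlrp3 (n = 4 each). Igf1 rose in APPPS1 minus WT at 6 months too (2.94 ± 0.45). Prnp rose with the transgenes at 4 and 6 months but did not pass at 12 months (57.6 ± 13.1 against 36.8 ± 9.61 CPM).

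Gh and Prl, hormones of the pituitary, stood at 1590 and 779 CPM in NLRP3_4m replicate 15 and at most at 0.269 CPM in the rest of its group. In Xist, female libraries had at least 352 CPM and male ones at most 9.93 CPM, and the Y-linked genes summed to at most 2.61 CPM in females and at least 312 CPM in males. The 6 groups with both sexes gave 21 libraries to the test of sex, since the library labelled APPPS1_12m_Mxo4 replicate 56 was left out of it.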
